A study of Epinephelus coioides with 6 samples.

How the data were processed

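Gonads of the orange-spotted grouper, Epinephelus coioides, were taken at 80, 120 and 180 days post-hatching (dph), and the RNA of single cells was sequenced from 2 suspensions per age. Per the labels' protocols, fresh gonads were mixed before dissociation, with n = 30 at 80dph, 20 at 120dph and 5 at 180dph. The tissue was digested with collagenase, strained, and loaded on a 10x Genomics 3' kit. The series' design text calls the suspensions biological duplicates, and no source used here says whether each came from its own pool of fish. The replicates may therefore be technical, and every p-value measures only the spread between these samples.

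The deposited values are raw UMI counts per gene and barcode, 1 matrix per library, with no normalization. Per the file headers the matrices were written by Cell Ranger 5.0.0, while the submitters' processing notes give Cell Ranger 2.1.1. The genome build and the annotation are not given in the sources used here. Each matrix listed the same 24607 IDs: 23879 genes, 303 noncoding genes, 412 pseudogenes by their prefix, and 13 mitochondrial protein genes with names. The files do not pair the other IDs with names, and 0 of them matched the reference table, so no symbol was taken from an ID. Cell classes, the 34 gene lists and the sex differentiation genes fixed beforehand could therefore not be looked up and were not analysed here; clusters and cell sets carry numbers only.

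The libraries held 6456 to 26019 barcodes and 71098168 to 109201608 UMIs. Barcodes with under 200 genes or over 20% mitochondrial UMIs were removed. Doublet scores came from Scrublet in scanpy 1.11.5, and the highest scores were removed at a rate of 0.8% per 1000 barcodes of the library. The automatic threshold of the same tool was not used, since it marked 0.201% of the barcodes of 80dph replicate 2 and 52.3% of those of 120dph replicate 1. This left 69483 of 83160 barcodes.

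Counts were scaled to 10000 per cell and log transformed, and 2000 variable genes and 30 principal components fed a graph of 15 neighbours, clustered by the Leiden method at resolution 1.0 (igraph 0.11.9, leidenalg 0.10.2). This gave 51 clusters. A cluster with over 90% of its barcodes from 1 library was called held by that library. Counts were summed per library over all kept barcodes, here called the whole suspension, and per library and cluster where every library of both ages held at least 50 cells. Sums were tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, after its filter on low counts and TMM scaling, with no covariate. For the whole suspension all 6 libraries entered 1 fit. A cluster's fit held only the ages whose libraries all had at least 50 cells. For clusters 9, 13, 19 and 21 these were 80dph and 120dph. P-values were adjusted by the Benjamini-Hochberg method over the genes of each test, at a threshold of 0.05, and all tests were two-sided. With 2 samples against 2, an exact permutation test cannot give a p below 0.333, so calls rest on the spread edgeR shares between genes.

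In 19 of 20 comparisons of a cluster between ages, at least 1 of the 10 genes leading that cluster itself changed. Of all genes tested in a comparison, 1.475% to 55.41% changed, so in most comparisons this would be met by any 10 genes. It does not show that leading genes changed more than others. The report draws no change of cell sets with age from the sizes of these clusters, and the planned test of them is given in the closing section as counts only. Shares of cells were compared instead over cell sets from a second clustering. It left out every gene called with age inside a cluster (10063 genes) and the barcodes of clusters held by 1 library, and kept 55572 cells in 46 sets. This second clustering was chosen after seeing the data; resolutions 0.1, 0.3 and 1.0 had been viewed before resolution 1.0, that of the design, was used. Genes could be called with age only in clusters shared by ages, so a set found mostly at 1 age may still be set apart by genes that change with age. Cell numbers of the 41 sets with at least 100 cells were tested with the edgeR quasi-likelihood test, adjusted over sets and comparisons together, and the 18 sets with at least 1000 cells are described. Shares are given as the mean ± SD of 2 libraries, and bars in the plots of shares are exact Clopper-Pearson 95% intervals, which cover counting error only.

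The tests, the filters on cells and genes, the lists and the rule for named genes were fixed before the data were examined. By that rule, where the files pair no names with IDs, at most 2 IDs that rose and 2 that fell are named, those with the largest log2 change from 80dph to 180dph among changed genes of at least 32 CPM on average (UMIs scaled to a fixed library total) whose ages did not overlap. The use of that comparison to choose them, and the description of the 13 mitochondrial genes as a group, were decided after the files showed which IDs carry names.

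The procedures were tested on simulated data. In the whole suspension from 80dph to 120dph (20733 genes, 200 of them changed), 7.46% of 2-fold, 71.6% of 4-fold and 87.9% of 8-fold changes were recovered, with 6 false calls among 117. In cluster 4 (11281 genes) the shares recovered were 43.3%, 94.0% and 95.5%, with 5 false calls among 160. For the cell sets from 80dph to 120dph, over 100 simulations of 41 sets, 1.5% of 2-fold, 23% of 4-fold and 61.5% of 8-fold changes were recovered, with 0.03 false calls per simulation. Under that setting many changes of share would be missed. The simulations changed few sets in 1 age, with 1 common dispersion, and gave 1.75 calls each, against 15 in the data. With more changes the adjusted threshold is easier to pass, so recovery and false calls in the data may differ.

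Alternatives were another scaling and test (DESeq2 1.42.0), no filter on low counts, only the groups compared, the replicate number as a block, each library left out in turn, other filters on cells, other resolutions, and barcodes of clusters held by 1 library left out or kept.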

Results

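Gonad suspensions of the orange-spotted grouper, a fish that matures first as a female and can later turn male, were profiled at 3 ages, 80, 120 and 180 days post-hatching, with 2 libraries per age. The libraries held 97723025 and 71098168 UMIs at 80dph, 101189124 and 109201608 at 120dph, and 99122209 and 89988928 at 180dph. After filtering, 7455 and 5737 barcodes were kept at 80dph, 20383 and 12698 at 120dph, and 11335 and 11875 at 180dph. The kept barcodes carried a median of 5549 and 4938 UMIs at 80dph, 2568 and 4943.5 at 120dph, and 6311 and 5164 at 180dph. Across genes, log2 CPM correlated between the replicates of an age at r = 0.973 at 80dph, 0.983 at 120dph and 0.968 at 180dph; genes are not independent replicates.

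The library 120dph replicate 1 stood apart from the other 5. Its shallowest barcode held 1399 UMIs, against 500 in each of the others, and 13770 of its kept barcodes, 67.6%, fell in 11 clusters made almost wholly of that library. In 120dph replicate 2 the share in such clusters was 1.00%, and in the other 4 libraries it was at most 0.0523%. Mitochondrial genes took 0.729% and 0.913% of the kept UMIs at 80dph, 2.66% and 1.84% at 120dph, and 1.42% and 1.58% at 180dph. Over every deposited barcode the shares were 2.097% and 1.31%, 3.096% and 2.12%, and 1.53% and 1.69%.

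**Figure D1:**
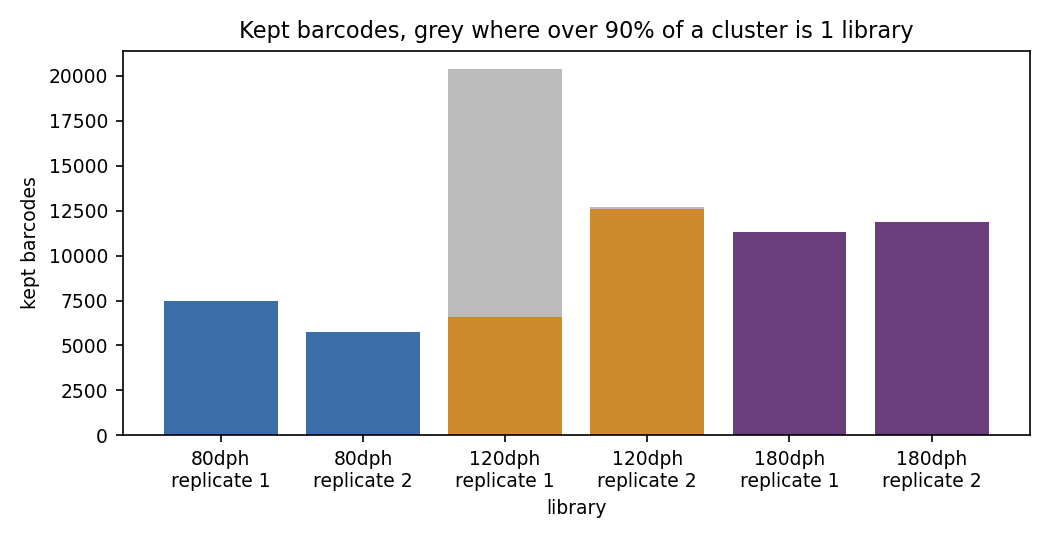
Kept barcodes per library (vertical axis, number of barcodes), with the part in clusters of which over 90% came from 1 library in grey. The grey part is 13770 of 20383 barcodes in 120dph replicate 1 and 127 of 12698 in 120dph replicate 2.

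The comparison of 120dph with 80dph asks which cells and genes change between the earliest ages sampled. Cell set 2 grew from 2.11% ± 0.147 of the cells at 80dph to 17.1% ± 0.406 at 120dph (SD, n = 2), a log2 change of 3.02 with an adjusted p of 0.00122 by the edgeR quasi-likelihood test. Cell set 9 grew from 1.62% ± 0.911 to 10.6% ± 0.0814 (SD, n = 2), a log2 change of 2.70 with an adjusted p of 0.00426 by edgeR. Its shares at 80dph were 0.979% and 2.27%, and over the alternatives its log2 change ranged from 1.58 to 3.43, the highest without 80dph replicate 2. Cell set 7 shrank from 15.04% ± 1.44 to 3.34% ± 1.33 (SD, n = 2), a log2 change of -2.17 with an adjusted p of 0.0170 by edgeR. Here and below, shares in 120dph replicate 1 are of the 6613 cells left without its barcodes in clusters held by 1 library. Over all kept barcodes, cluster 1, on which set 2 drew, held 7.14% of 120dph replicate 1 and 23.6% of replicate 2. Cluster 14, on which set 9 drew, held 3.35% and 8.58%. The SDs and p-values of shares rest on that dropping and do not cover this difference. Among the 41 sets tested, 9 rose and 6 fell. Without 80dph replicate 1 the adjusted p of set 7 was 0.0622, and without 120dph replicate 1 it was 0.133, with log2 changes of -2.07 and -1.81. The number of sets that changed, 15 in all, was 8 without 80dph replicate 1, 9 without 120dph replicate 1, 7 without 120dph replicate 2 and 9 without 180dph replicate 1, and it was 7 of 17 sets tested at resolution 0.1 and 9 of 24 at resolution 0.3.

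Of the 13 mitochondrial protein genes, 7 rose from 80dph to 120dph in the whole suspension and the others did not pass the test. The 3 subunits of cytochrome c oxidase, the last enzyme of the respiratory chain, were among them. COXI rose from 918 ± 56.3 to 3001 ± 526 CPM (UMIs scaled to a fixed library total, SD, n = 2). Its log2 change was 1.40 (SE 0.204, adjusted p = 0.00701, edgeR). COXII rose by 1.17 on the log2 scale and COXIII by 1.21. Here and below, log2 changes of genes come from the fit with TMM scaling, which CPM lack, so they can differ from the ratios of the CPM given. Both mitochondrial subunits of ATP synthase rose, ATP6 by 1.30 and ATP8 by 1.31, as did ND4L of complex I by 1.08 and CYTB of complex III by 0.97. Levels in the whole suspension are sums over all cells, so here and below a change in the cells present may give or add to such changes. Cluster 5, with a median of 12230.5 UMIs and 0.204% mitochondrial UMIs per barcode, held 29.7% and 25.7% of the kept barcodes at 80dph. At 120dph it held 0.113% and 0.504%. How much this added to the rise was not measured. Within clusters, at least 1 mitochondrial gene rose in clusters 4, 11, 13, 18, 21 and 24. None passed as a rise in clusters 9, 10, 14, 19 and 29. In cluster 29 CYTB fell by 0.31 and ND6 by 1.47 on the log2 scale (adjusted p = 0.0312 and 0.0296, edgeR). With 1 library left out both kept their direction there, with log2 changes from -0.37 to -0.28 for CYTB and from -2.30 to -0.69 for ND6. In clusters 13 and 21 none of the rises passed without 80dph replicate 1 or without 80dph replicate 2, while the log2 change of COXI stayed between 1.06 and 1.11 in cluster 13 and between 0.65 and 0.87 in cluster 21 as each library was left out. In cluster 14, 2 and 4 genes passed as rises without 80dph replicate 1 and replicate 2, and in cluster 29, 3 did without 120dph replicate 2. With 1 library left out the 7 genes kept their direction, and the log2 changes ranged from 1.14 to 1.504 for COXI, 0.73 to 1.40 for COXII, 0.79 to 1.43 for COXIII, 0.80 to 1.57 for ATP6, 1.02 to 1.47 for ATP8, 0.76 to 1.49 for ND4L and 0.83 to 1.12 for CYTB. Fewer of them passed the test when their age had 1 sample. ND4L passed in 8 of 16 alternatives, and it missed the threshold with both ages whole in the fit of the 2 ages alone (adjusted p = 0.0558), without 180dph replicate 1 (0.0587), without 180dph replicate 2 (0.0524) and without barcodes of clusters held by 1 library (0.0622). Without 120dph replicate 1 the lowest adjusted p of the 13 genes was 0.0672, for COXI; 1 gene rose without 80dph replicate 1, 3 without 80dph replicate 2, 4 without 120dph replicate 2, and 1 with every deposited barcode, where the changes themselves were smaller, with log2 changes of 0.62 for COXI, 0.14 for COXII and -0.05 for CYTB.

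In the whole suspension, 2396 of 20733 tested genes rose from 80dph to 120dph and 2323 fell, with an adjusted p under 0.05 by edgeR. Eco_gene_10020368 fell from 417 ± 248 to 0.214 ± 0.00332 CPM (SD, n = 2), a log2 change of -11.24 (SE 0.73, adjusted p = 0.00178, edgeR), and the summed counts gave a ratio of 2059 with a 95% counting interval of 1494 to 2925; without 80dph replicate 1 the log2 change was -10.42. Within clusters, 11 clusters could be compared and gave 12524 calls over 6419 genes; 203 genes rose and 50 fell in at least 1 of every 2 clusters tested. These became 54 and 9 without 80dph replicate 1, 34 and 17 without 80dph replicate 2, and 76 and 33 without 120dph replicate 1. The 1303, 1854 and 847 genes changed in clusters 9, 13 and 21 became 0 without 80dph replicate 1 and 0 without 80dph replicate 2, and the 344 in cluster 19 became 0 without 80dph replicate 2. The fits of clusters 9, 13, 19 and 21 held only 80dph and 120dph, so leaving out a library left fewer samples to measure the spread than in the whole suspension. In cluster 4, 1760 of 11281 genes rose and 1204 fell. These 2964 genes became 1753 without 80dph replicate 1, 1394 without 80dph replicate 2, 1496 without 120dph replicate 1, 1750 without 120dph replicate 2 and 1801 with the DESeq2 Wald test. The 4719 genes changed in the whole suspension became 2145 without 80dph replicate 1, 2576 without 80dph replicate 2, 838 without 120dph replicate 1 and 1223 without 120dph replicate 2. The calls within clusters numbered 6748 without 80dph replicate 1, 5062 in 12 clusters without 80dph replicate 2, and 7144 with the DESeq2 Wald test.

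The comparison of 180dph with 120dph asks what changes at the later step. At 180dph a large part of the gonad cells lay in sets that were rare before. The sets given here drew largely on clusters 2, 7, 8, 12 and 22 of the first clustering. Those clusters held too few cells at 80dph and 120dph to be compared between ages, so no gene was called with age in them. The sets may therefore still be set apart by genes that change with age. Cell set 3 grew from 0.524% ± 0.0572 at 120dph to 18.4% ± 6.21 at 180dph (SD, n = 2), a log2 change of 5.13 with an adjusted p of 0.000238 by edgeR. Set 6 grew from 0.872% ± 0.0149 to 12.8% ± 1.24, set 8 from 0.810% ± 0.00929 to 9.40% ± 0.638, and set 10 from 0.137% ± 0.0872 to 9.004% ± 0.777 (SD, n = 2 each). The log2 change of set 10 was 5.97, and 6.87 without 120dph replicate 2. Set 14 grew from 0.0585% ± 0.0185 to 5.29% ± 0.905 and set 16 from 0.190% ± 0.0123 to 4.95% ± 0.797 (SD, n = 2 each).

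Over the same step the shares of other sets fell, among them sets 2 and 9, whose shares had grown by 120dph. Shares are parts of a whole, so a rise of some sets lowers the shares of the others even where their cells did not become fewer. This holds for each comparison of ages, and numbers of cells per gonad were not measured. Set 2 fell from 17.1% ± 0.406 to 4.01% ± 1.19 (SD, n = 2; log2 change -2.09, adjusted p = 0.00600, edgeR) and set 9 from 10.6% ± 0.0814 to 0.274% ± 0.0885 (SD, n = 2; log2 change -5.26, adjusted p = 0.000295, edgeR). Set 5 fell from 13.2% ± 0.745 to 2.103% ± 0.266, set 13 from 4.50% ± 0.655 to 0.484% ± 0.435, set 17 from 3.41% ± 0.325 to 0.462% ± 0.216 and set 18 from 2.78% ± 0.542 to 0.564% ± 0.0241 (SD, n = 2 each). The log2 change of set 13 was -3.21, and it was -2.503 without 180dph replicate 1 and -4.66 without 180dph replicate 2. In all, 10 sets rose and 11 fell of 41 tested. The changed sets numbered 12 of 17 tested at resolution 0.1 and 35 of 59 at resolution 2.0.

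**Figure D2:**
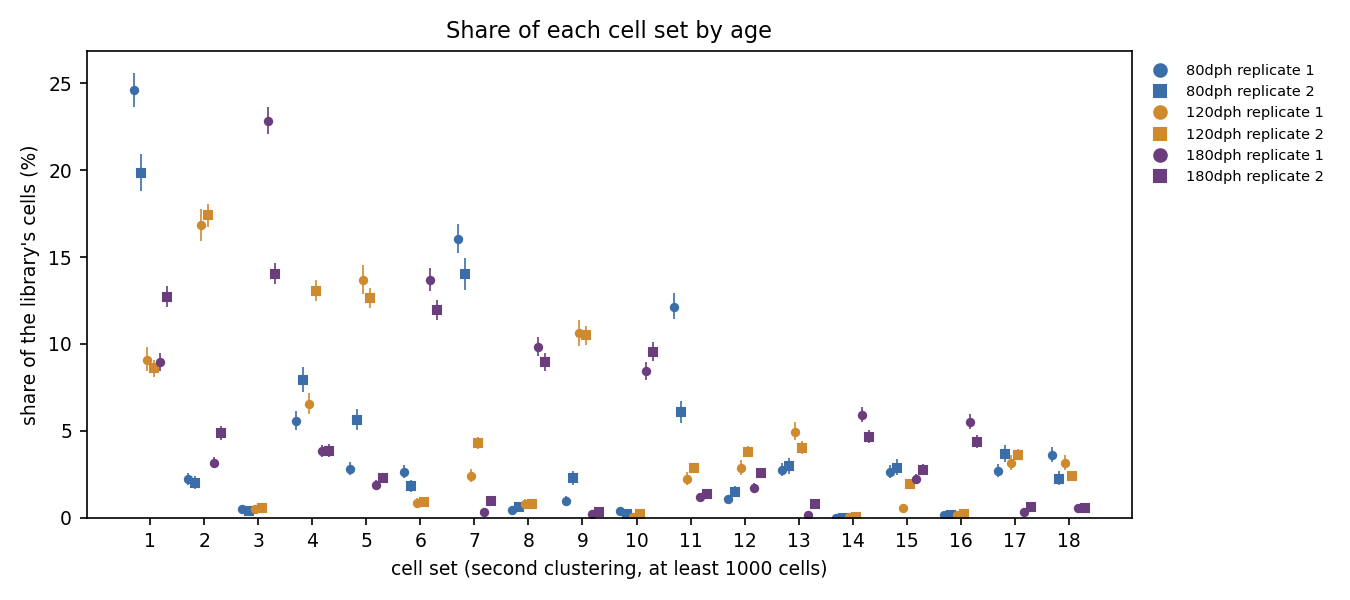
Share of each library's cells (vertical axis, percent) in the 18 cell sets with at least 1000 cells; colours are ages, circles replicate 1, squares replicate 2, and bars exact 95% counting intervals. Sets 3, 6, 8, 10, 14 and 16 stand highest at 180dph, sets 2, 5 and 9 at 120dph, and sets 7 and 11 at 80dph.

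Of the 13 mitochondrial genes, 5 fell at this step and the other 8 did not pass the test. ND3, a subunit of complex I, fell furthest, from 91.2 ± 11.9 to 20.1 ± 1.04 CPM (SD, n = 2), a log2 change of -2.17 (SE 0.27, adjusted p = 0.00293, edgeR). ATP6 fell by 1.33 on the log2 scale, ND1 by 1.11, ND4L by 1.04 and ATP8 by 0.98. ND3 also fell in 5 of the 6 clusters that could be compared, though not in cluster 1 without 120dph replicate 1 or in cluster 11 without 120dph replicate 2, where its log2 changes of -1.13 and -1.07 missed the threshold. Its share of all mitochondrial UMIs was 0.546% and 0.696% in the libraries at 80dph, 0.374% and 0.450% in those at 120dph and 0.136% and 0.132% in those at 180dph. Without 120dph replicate 1, and likewise without 180dph replicate 1, 1 gene fell; 3 fell without 120dph replicate 2, and 3 without 180dph replicate 2. With 1 library left out the log2 changes kept their direction and ranged from -2.39 to -1.94 for ND3, -1.71 to -0.84 for ATP6, -1.38 to -0.66 for ND1, -1.17 to -0.797 for ND4L and -1.22 to -0.71 for ATP8. Without barcodes of clusters held by 1 library the log2 change of ND4L was -0.82 and missed the threshold (adjusted p = 0.0618, edgeR).

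**Figure D3:**
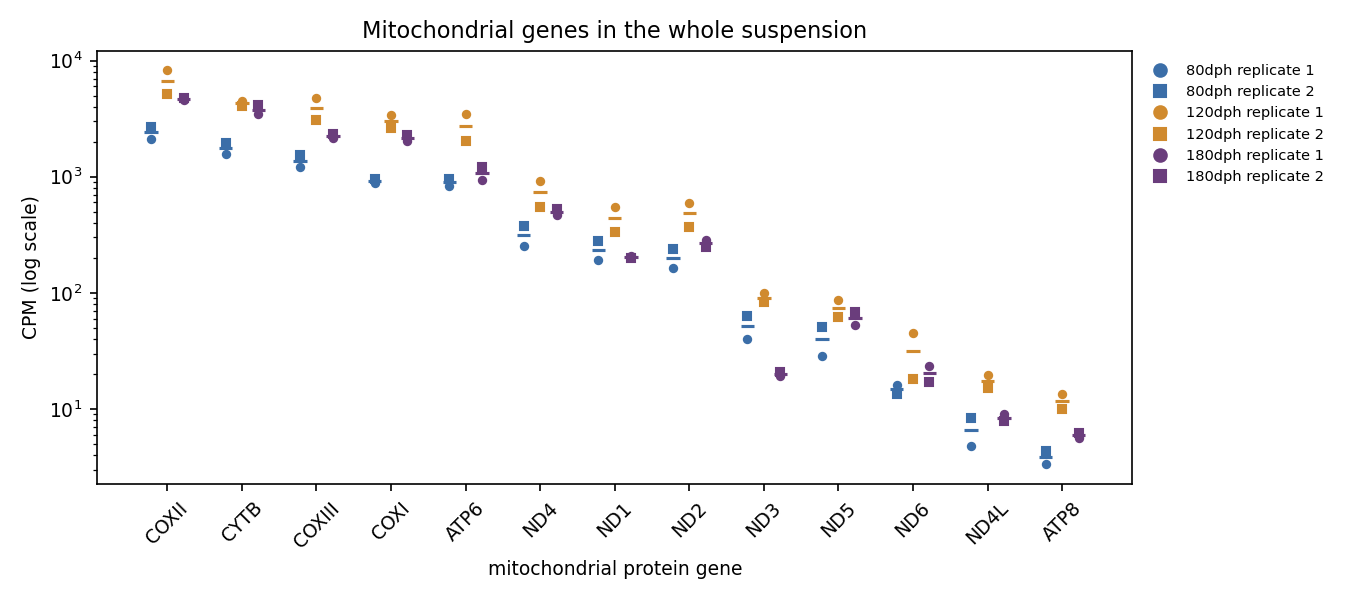
Level of the 13 mitochondrial protein genes in the whole suspension (vertical axis, CPM, log scale); colours are ages, circles replicate 1, squares replicate 2, and short lines the means of 2 libraries. ND3 has means of 51.7, 91.2 and 20.1 CPM at 80dph, 120dph and 180dph.

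In the whole suspension, 2829 genes rose and 3175 fell from 120dph to 180dph. Eco_gene_10014294 rose from 0.191 ± 0.0125 to 711 ± 878 CPM (SD, n = 2), a log2 change of 11.75 (SE 1.502, adjusted p = 0.00306, edgeR), and Eco_gene_10017777 rose from 0.0874 ± 0.0430 to 206 ± 242 CPM (SD, n = 2), a log2 change of 11.09 (SE 1.38, adjusted p = 0.00282, edgeR). Eco_gene_10010437 fell from 57.7 ± 30.4 to 0.0241 ± 0.0156 CPM (SD, n = 2), a log2 change of -11.11 (SE 1.56, adjusted p = 0.00417, edgeR). For each of the rising IDs the level in 180dph replicate 1 was far above that in replicate 2, 1332 against 90.4 CPM for Eco_gene_10014294 and 377 against 34.5 CPM for Eco_gene_10017777. Without 180dph replicate 1 their log2 changes were 9.06 and 8.79, and without 180dph replicate 2 they were 12.60 and 11.90; without 120dph replicate 1 that of Eco_gene_10017777 was 11.71. The log2 change of Eco_gene_10010437 was -10.40 without 120dph replicate 2 and -11.76 without 180dph replicate 1. Within 6 clusters there were 10976 calls over 6571 genes; 391 genes rose and 555 fell in at least 1 of every 2 clusters. These became 181 and 210 without 120dph replicate 1, 80 and 159 without 120dph replicate 2, 65 and 81 in 11 clusters without 180dph replicate 1, and 204 and 217 without 180dph replicate 2. The 386 genes changed in cluster 31 became 0 without 180dph replicate 1. The 6004 genes changed in the whole suspension became 2060 without 120dph replicate 1 and 2198 without 120dph replicate 2. The calls within clusters numbered 5945 without 120dph replicate 1, 7228 in 7 clusters without 120dph replicate 2, 7019 without 180dph replicate 2, 3094 in 4 clusters at resolution 2.0 and 6978 in 3 clusters with at least 500 genes per cell.

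The comparison of 180dph with 80dph spans the whole period. Cell sets 3, 8, 10 and 16, each at most 0.551% of the cells at 80dph, held 18.4% ± 6.21, 9.40% ± 0.638, 9.004% ± 0.777 and 4.95% ± 0.797 at 180dph (SD, n = 2 each). Set 14 had 0 of 13187 cells at 80dph, which allows a share of up to 0.0227%, a floor of 3 cells over both libraries. Its 5.29% ± 0.905 at 180dph (SD, n = 2) was 232.55 times that floor. Over the alternatives the log2 changes ranged from 5.01 to 6.06 for set 3, 3.86 to 8.03 for set 8, 4.58 to 5.64 for set 10 and 3.66 to 11.401 for set 16, always as a rise. The upper end for set 16 would leave under 1 cell of 13187 at 80dph, so it is not a measured size. Set 14 rose in each alternative with a match as well. Its log2 change is not a measured size, since it had 0 cells at 80dph, and none is given. Set 7 fell from 15.04% ± 1.44 to 0.639% ± 0.442 (SD, n = 2), a log2 change of -4.55 with an adjusted p of 0.000758 by edgeR. Its shares at 180dph were 0.327% and 0.952%, and over the alternatives its log2 change ranged from -5.52 to -3.98, the lowest without 180dph replicate 2 and the highest without 180dph replicate 1. Set 11 fell from 9.12% ± 4.29 to 1.29% ± 0.135 (SD, n = 2), a log2 change of -2.82 with an adjusted p of 0.00258 by edgeR, which ranged from -3.67 to -2.14 over the alternatives. Of 41 sets, 11 rose and 13 fell, and the changed sets numbered 9 of 17 tested at resolution 0.1, 14 of 24 at resolution 0.3 and 37 of 59 at resolution 2.0.

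From 80dph to 180dph, COXI rose by 0.94 and CYTB by 0.81 on the log2 scale, and ND3 fell by 1.66 (adjusted p = 0.00482, edgeR), from 51.7 ± 16.8 to 20.1 ± 1.04 CPM (SD, n = 2). The other 10 mitochondrial genes did not pass the test. With every deposited barcode, the log2 changes of COXI and CYTB were 0.13 and -0.25 and neither passed the test, while ND1 fell by 1.48 and ND2 by 0.93 (adjusted p = 0.0113 and 0.0375, edgeR). Without 80dph replicate 1, and likewise without 80dph replicate 2, neither passed it, with adjusted p-values of 0.0671 and 0.0619 for COXI and 0.122 and 0.0577 for CYTB by edgeR, while the log2 changes were 0.88 and 0.94 for COXI and 0.65 and 0.93 for CYTB. CYTB also missed the threshold without 120dph replicate 1, without 120dph replicate 2 and without 180dph replicate 2, with adjusted p-values of 0.0523, 0.0520 and 0.0763 by edgeR and log2 changes of 0.79, 0.79 and 0.51. Within the 3 clusters compared, 6 mitochondrial genes rose and 1 fell in cluster 4, 8 rose in cluster 11, and 3 fell in cluster 10. With 1 library left out each kept its direction, but fewer passed the test in clusters 10 and 11. The log2 change of ATP6 then ranged from -1.09 to -0.45 in cluster 10 and from 0.53 to 0.98 in cluster 11. That of ND3 in cluster 10 ranged from -2.46 to -2.24, and that of COXI in cluster 11 from 0.96 to 1.67.

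In the whole suspension, 4202 genes rose and 4392 fell over the period. Eco_gene_10014294 had 8 UMIs at 80dph and 120855 at 180dph, a ratio of CPM of 14265 with a 95% counting interval of 7239 to 33041 (log2 change 13.27, adjusted p = 0.00217, edgeR). Eco_gene_10017777 had 8 and 34849, a ratio of 4113 with an interval of 2087 to 9528. Eco_gene_10020368 had 67589 UMIs at 80dph and 3 at 180dph, a ratio of 23860 with an interval of 8164 to 1.157e+05, and Eco_gene_10010437 had 75980 and 4, a ratio of 20117 with an interval of 7857 to 73834. These intervals cover counting error only, and the ratios, unlike the log2 changes, are without TMM scaling. At 80dph the level of Eco_gene_10010437 was 105.1 CPM in replicate 1 and 1013 CPM in replicate 2, and its log2 change of -14.68 was -12.36 without 80dph replicate 2, -15.57 without 80dph replicate 1 and -15.39 without 180dph replicate 1. The log2 changes of Eco_gene_10014294 and Eco_gene_10017777 were 10.52 and 9.13 without 180dph replicate 1 and 14.12 and 12.30 without 180dph replicate 2. That of Eco_gene_10020368, -14.68, was -13.89 without 80dph replicate 1 and -13.95 without 180dph replicate 2; without 180dph replicate 1 the ID had 0 UMIs at 180dph and no fold is given. Within the 3 clusters that could be compared there were 7358 calls; 727 genes rose and 501 fell in at least 1 of every 2 clusters, which became 346 and 230 without 80dph replicate 1, 341 and 230 without 80dph replicate 2, 248 and 175 in 8 clusters without 180dph replicate 1, and 353 and 163 without 180dph replicate 2. In cluster 4, 2529 of 11281 genes rose and 2221 fell, and these 4750 genes became 2968 without 80dph replicate 2. The 8594 genes changed in the whole suspension became 5157 without 80dph replicate 2. The calls within clusters numbered 4317 without 80dph replicate 2, 4893 without 180dph replicate 2, 12046 in 4 clusters at resolution 0.5, 1922 in 2 clusters at resolution 2.0, 1848 in 1 cluster with at least 500 genes per cell, 4188 in 3 clusters with doublets kept, and 3025 in 1 cluster from barcodes at or above the highest library minimum of UMIs.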

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

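Chosen after the result was seen were barcodes at or above the highest library minimum of UMIs, barcodes of clusters held by 1 library left out, and all alternatives of the cell sets. Where a value moved the cause was not tested, except that leaving out a library leaves that age with 1 sample, which edgeR assumes to vary like the other ages.

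The number of genes changed in the whole suspension ranged with 1 library left out from 838 to 5848 for 120dph against 80dph, 2060 to 5525 for 180dph against 120dph, and 5157 to 8091 for 180dph against 80dph, and stayed within 1.5 times under every other alternative. With 1 library left out, calls within clusters ranged from 5062 to 13053, 5945 to 11249 and 4317 to 10177 in the same order, over 11 to 13, 6 to 11 and 3 to 8 clusters. They were 7144 by the DESeq2 Wald test for 120dph against 80dph; 3094 in 4 clusters at resolution 2.0 and 6978 in 3 with at least 500 genes, against 6, for 180dph against 120dph; and, for 180dph against 80dph, 12046 in 4 clusters at resolution 0.5, 1922 in 2 at resolution 2.0, 1848 in 1 with at least 500 genes, 4188 in 3 with doublets kept and 3025 in 1 with barcodes at or above the highest library minimum, against 3. These totals follow the number of clusters compared as well as the calls in each.

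Changed cell sets ranged from 7 to 12, 16 to 22 and 19 to 25 with 1 library left out. They numbered 7, 12 and 9 of 17 tested at resolution 0.1, 9 and 14 of 24 at resolution 0.3 for 120dph and 180dph against 80dph, and 35 and 37 of 59 at resolution 2.0 for 180dph against 120dph and 80dph, so the count moves with the number of sets. A set was matched across clusterings only where over 0.5 of the cells in either were shared; unmatched sets have no value. The best match of set 5 at resolution 2.0 had a log2 change of 3.20 from 80dph to 180dph (adjusted p = 0.00194, edgeR), against -1.002. Sets 1, 6 and 12 no longer passed the threshold from 80dph to 120dph in 9 of 12, 8 of 10 and 9 of 11 alternatives, with the direction kept and log2 changes from -1.97 to -1.12, -1.75 to -0.18 and 1.14 to 2.05; sets 2, 3, 8, 10 and 16 kept the direction and side of the threshold of each change the report gives in each alternative with a match. The size of a change moved more: between 120dph and 180dph the log2 change ranged from 4.54 to 5.82 for set 3, 2.03 to 5.78 for set 6, 3.46 to 5.98 for set 8, -5.63 to -4.598 for set 9, 5.13 to 6.87 for set 10, -4.66 to -2.18 for set 13, 6.12 to 7.11 for set 14, 3.702 to 7.23 for set 16, -4.901 to -2.47 for set 17 and -5.04 to -2.08 for set 18.

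The first clusters by number, the planned comparison of shares, gave 4, 15 and 16 changed of 46. With 1 library left out they ranged from 3 to 21, 0 to 25 and 1 to 27 (26 and 24 of 46 at an unadjusted p under 0.05 with all libraries for 180dph against 120dph and 80dph). They were 21, 38 and 31 of 66 at resolution 2.0, 14, 23 and 27 of 45 with doublets kept, 12, 24 and 29 of 37 without barcodes of clusters held by 1 library, and 11 and 26 of 43 with at least 500 genes for 120dph against 80dph and 180dph against 120dph.

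Deviations of same-numbered libraries correlated at 0.017, 0.040 and 0.12 across genes, which leaves pairing by number open. With the replicate block, 16 first clusters changed instead of 4 for 120dph against 80dph, 25 instead of 15 for 180dph against 120dph, and 11, 21 and 23 cell sets.

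The calls of mitochondrial genes depended on the cell filter. With every deposited barcode CYTB had log2 changes of -0.046 (120dph against 80dph, adjusted p = 0.913, edgeR) and -0.25 (180dph against 80dph, adjusted p = 0.484), while ND2 and ND1 fell with -0.93 (adjusted p = 0.0375) and -1.48 (adjusted p = 0.0113) for 180dph against 80dph. ND3 fell in all 16 alternatives, with log2 changes from -2.39 to -1.94 between 120dph and 180dph and from -2.72 to -1.35 between 80dph and 180dph. The 4 named IDs kept every call in all 16 alternatives.

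Tests by named cell class, of gene lists and of sex differentiation genes were not run, since the files do not pair IDs with names. Depth limits small shares: 0 cells of 13187 allow up to 0.0227%.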

Other observations

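The tests of doublets by UMIs and by score, of thinned abundant genes and of ND3 were chosen after the result was seen, and the cell sets come from a clustering chosen after the data were seen.

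Smaller cell sets moved with age as well. Set 19 grew from 0.282% ± 0.0948 of the cells at 80dph to 3.49% ± 0.00630 at 120dph (SD, n = 2), a log2 change of 3.63 with an adjusted p of 0.00292 by the edgeR quasi-likelihood test, and fell to 0.502% ± 0.422 at 180dph, a log2 change of -2.79 with an adjusted p of 0.00778. Set 32 fell from 0.914% ± 0.0549 at 120dph to 0.0814% ± 0.0278 at 180dph (SD, n = 2), a log2 change of -3.46 with an adjusted p of 0.00117 by edgeR. Set 30 grew from 0.0469% ± 0.0236 to 1.30% ± 0.0975 over the same step (SD, n = 2), a log2 change of 4.68 with an adjusted p of 0.000805 by edgeR. The alternatives were not followed for these smaller sets.

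Barcodes of very high UMI count were a feature of the youngest gonads. At 80dph, 90 and 61 barcodes held at least 100000 UMIs, and they carried 12.8% and 12.2% of the UMIs of their libraries. At 120dph there were 8 and 20 such barcodes with 0.918% and 2.42% of the UMIs, and at 180dph 4 and 3 with 1.39% and 0.477%. Of the 85 and 58 that were kept at 80dph, 74 and 47 lay in cluster 5, with a median of 5724 and 5701 genes detected over all such barcodes.

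Most kept barcodes of 120dph replicate 1 lay in clusters of their own, and droplets with free RNA and no cell are a candidate explanation. Their summed profile correlated across genes with the library's other kept barcodes at r = 0.988, better than each of 9 clusters compared (highest r = 0.852), which such droplets would give, but so would a mixture of many cell types. The variance between barcodes was 1.19 times the sampling variance, a test that on simulated mixtures had no power, and 1.24 times for abundant genes at one depth, against 1.00 simulated from one profile, 1.30 simulated from the profiles of 2 clusters and 2.102 in the library's other barcodes, so free RNA and shallow cells cannot be told apart. Doublets of the library's other cells would carry more UMIs, while the median of these barcodes was 0.520 times that of the others; their median doublet score was higher, 0.271 against 0.179 or 1.51 times, so doublets of shallower cells stay open, as a mixed profile alone may also raise the score. No biological explanation was tested, since the replicate is no group of the design.

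ND3 fell further than the other mitochondrial genes from 120dph to 180dph in the whole suspension and in 4 of 6 clusters; in cluster 10 ND4L fell further (log2 change -2.39 against -2.22) and in cluster 31 ATP6 did (-0.99 against -0.94). Its share of mitochondrial UMIs was already lower at 120dph, 0.374% and 0.450%, than at 80dph, 0.546% and 0.696%. The limit on mitochondrial UMIs per cell is not the cause, since over every deposited barcode the ND3 share of mitochondrial UMIs still had a log2 change of -1.65. Within clusters the ND3 change minus the median of the other mitochondrial genes had a median of -1.55, so the fall was not seen only in the summed cells. A change in the cells present cannot be excluded by this, since free RNA from other cells could carry it into each cluster and was not measured. A sequence variant among the few fish pooled at 180dph and a change with age may each account for it; neither was tested.

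Some genes changed the same way in at least 1 of every 2 clusters tested. Free RNA from other cells may give or add to such calls. From 80dph to 120dph 32.8% of these calls lay above the level of the whole suspension in both libraries of the higher age, 37.3% from 120dph to 180dph and 42.2% from 80dph to 180dph. This would limit free RNA only if its profile were that of the kept barcodes, which was not measured, and more free RNA at the other age could also dilute a cluster's own genes. Calls that coincide by chance add to the numbers as well. From 80dph to 180dph, 42.11% of the genes tested changed in cluster 4, 12.76% in cluster 10 and 21.35% in cluster 11, and calls in 2 of these 3 clusters sufficed. The number expected from chance was not computed. Chance overlap, free RNA and a response to age shared by cell types all stay open.

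Pairs of consecutive numbers in which both IDs changed the same way were more frequent than shuffled calls would give. The shuffles moved calls and directions together, so neighbours that merely tend to be called together would also give an excess. Agreement of direction among changed pairs was not measured by itself. Over 17470 pairs of consecutive numbers the ratio to the mean of 10000 shuffles was 1.44 from 80dph to 120dph, 1.39 from 120dph to 180dph and 1.21 from 80dph to 180dph, each with a permutation p of 0.0001, the smallest the shuffles can give. If numbers follow the genome, neighbouring genes may change together; reads shared between neighbouring copies would give the same and were not tested.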
